A study of Mus musculus with 12 samples.

How the data were processed

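Gene expression was measured in C2C12 cells, a mouse myoblast line that forms multinucleated myotubes in culture. Per the labels' protocols, myoblasts grew in medium with bovine calf serum, and confluent myoblasts were switched to horse serum with insulin and transferrin to differentiate. Total RNA was purified on columns and checked on a Bioanalyser, and biotin-labelled cRNA was hybridised to Illumina bead arrays. The 12 arrays fall into 4 groups of 3: myoblasts at 50% confluence, myoblasts at 95% confluence, and myotubes after 24 h and after 48 h of differentiation. The labels number the replicates but do not say whether they were separate cultures, so the p-values measure the spread between these samples.

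The values came from the authors' deposited table of normalized signal, taken as log2 intensities. Per the submitters' processing notes, RMA and lumi were used, with no role, order or version given. In every one of the 12 columns the 45281 values run from 6.319 to 15.253 around a median of 6.684. The columns hold a single set of values in different orders, as quantile normalization leaves them. A plain log2 scale and a variance-stabilized scale, which compresses dim signals, could not be told apart from the table, so fold changes of dim genes can be understated to an unknown extent. A table of signal before normalization names its columns by numbers that match no sample's labels, so its 24 columns of per-sample values were not used here. The planned background correction and normalization of that table were therefore not applied, and detection p-values were not used. The number of arrays limits the precision.

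Of the 45281 probes, 34885 were assigned to 1 gene, 18 to several and 10378 to none. For 34807 of the probes with 1 gene the symbol was looked up through the gene identifier. A probe was kept if it lay above the array median on all 3 arrays of at least 1 group, the rule set for a table without detection calls. This left 19403 probes with 1 gene, and each of the 11883 genes was represented by its kept probe with the highest mean. A second kept probe existed for 4848 genes. Genes are named by symbol, and no genome positions are given.

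Group means were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), with 8 residual and 3.59 prior degrees of freedom. This fit takes a single spread per gene for all groups, and the arrays of the 95% group varied more than the others. Standard errors of comparisons with the 95% group can therefore be too small. The comparisons were 24 h myotubes against 95% confluent myoblasts, 48 h myotubes against 50% confluent myoblasts, 48 h against 24 h myotubes, and 95% against 50% confluent myoblasts. A moderated F-test asked for a change at any stage. Genes passed at an adjusted p under 0.05 (Benjamini-Hochberg, 2-sided), and all adjusted p of single genes come from this fit.

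Gene lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists tested. Of 29 lists, 26 had at least 5 measured genes. The lists were myogenic transcription factors, sarcomere, excitation-contraction coupling and calcium handling, costamere and dystrophin complex, muscle energy metabolism, neuromuscular junction, and myoblast fusion and adhesion. Others held progenitor genes and inhibitors of myogenesis, DNA replication and G1/S, mitosis and G2/M, cell cycle exit, ribosome biogenesis, serum and growth factor response, YAP/TAZ-TEAD targets, the Notch pathway, the insulin-like growth factor system, imprinted genes, cholesterol synthesis, fatty acid synthesis, mitochondrial respiration, and hypoxia and glycolysis. The last held the unfolded protein and amino acid stress response, the interferon response, extracellular matrix and fibroblast-type markers, reference genes, and markers of osteoblasts, adipocytes, endothelial cells, and macrophages and leukocytes. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance 1 way, were run as alternatives. Counts adjusted over the list alone use the same fit with the p-values of the list's members only.

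The groups, comparisons, lists, thresholds and alternatives were set before the data were examined, except where stated. The genes named in each comparison were the 7 with the largest rise and the 7 with the largest fall among genes past the threshold whose arrays did not overlap. To these were added 12 fixed genes (Myod1, Myog, Myf5, Mef2c, Pax7, Myh3, Acta1, Ckm, Cdkn1a, Ccnd1, Mki67, Id3). For each list past the threshold, up to 4 members that moved with the list and up to 2 that moved against it were added. The text prints the clearest of these, and members of lists that did not pass were chosen after their values were seen. Myf5 and Pax7 lay below the filter, with highest group means of 6.62 and 6.54, and Myh3 and Mki67 had no usable probe.

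Alternatives covered the filter, the choice of probe per gene, the variance model, array quality weights, fits to the 6 arrays compared, the replicate number as a block, and leaving out each array. Alternatives chosen after the data were seen were centring the arrays on expressed probes, a level filter of 7.5, and camera with an estimated correlation without array 3 of the 95% group or another array. The fit was tested on simulated data with 50 changed genes per effect size. At log2 changes of 0.25, 0.5, 1 and 2 it recovered 28, 90, 100 and 100% in the 24 h against 95% comparison and 38, 92, 100 and 100% in the 48 h against 50% comparison. Recovery was 24, 80, 98 and 100% in the 48 h against 24 h comparison and 26, 90, 98 and 100% in the 95% against 50% comparison. Calls among the unchanged genes numbered 11, 5, 11 and 16 in the same order. Camera called the list shifted by 0.5 in all 4 simulated comparisons and 0 of the unchanged lists. The simulated genes were drawn independently, so this does not test how correlation between members of a list affects the calls. Each simulated gene also had the same spread in all groups. The real arrays of the 95% group had residual SDs of 0.119 to 0.196, against 0.0576 to 0.0784 for the others. In comparisons with that group recovery can therefore be lower, and calls among unchanged genes more numerous, than simulated. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.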

Results

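Transcript levels were measured in C2C12 myoblasts at 50% and 95% confluence and in myotubes after 24 h and 48 h of differentiation, with 3 arrays per stage. Levels are log2 intensities, and 11883 genes were tested. The differences address how gene expression moves from growing myoblasts through confluence into early myotubes. Of these genes, 8578 (72.2%) passed the F-test for a change at any stage. Arrays correlated with their own group at r of 0.997 to 0.998, except in the 95% group, where array 3 correlated with the other 2 arrays at 0.985 and 0.986. That array had a residual SD of 0.196, against 0.0576 to 0.129 for the other 11 arrays. Along the second principal component, which held 18.9% of the variance, the 50% and 48 h arrays scored 11.4 to 21.1 and the 95% and 24 h arrays scored -19.7 to -4.58. The 24 h against 95% and 48 h against 50% comparisons lie within the sides of this split, and the other 2 comparisons cross it.

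**Figure D1:**
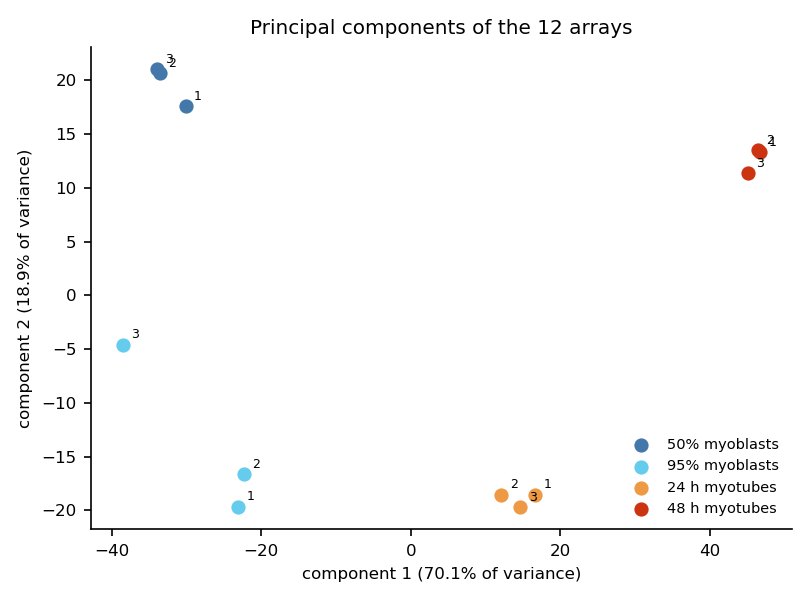
Scores of the 12 arrays on the first 2 principal components of the log2 values of the tested genes, coloured by stage and numbered by replicate. The horizontal axis holds 70.1% of the variance and orders myoblasts before 24 h and 48 h myotubes, and the vertical axis holds 18.9% and parts the 50% and 48 h arrays from the 95% and 24 h arrays.

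Myotubes at 24 h were compared with 95% confluent myoblasts to find what the first day of differentiation changed. The 7 largest rises were in Mylpf, Tnnc2, Actc1, Acta1, Myl4, Tnni2 and Atp2a1. Mylpf, a myosin regulatory light chain of fast muscle, rose from 8.01 ± 0.85 to 14.53 ± 0.23 (SD, n = 3), a log2 change of 6.52 (SE 0.33, adjusted p = 5.07e-08). Acta1, skeletal muscle alpha-actin, rose from 8.55 ± 0.52 to 14.41 ± 0.24, a log2 change of 5.87 (SE 0.23, adjusted p = 6.60e-09). At 24 h both lay near the highest value of the arrays, which can limit a rise. Myog, the transcription factor myogenin, rose by 4.62 (SE 0.20, adjusted p = 1.16e-08), and Ckm, muscle creatine kinase, rose by 3.30 (SE 0.11) from a level below the array median. Ccnd1, cyclin D1, fell, with a log2 change of -1.40 (SE 0.11, adjusted p = 1.38e-06).

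**Figure D2:**
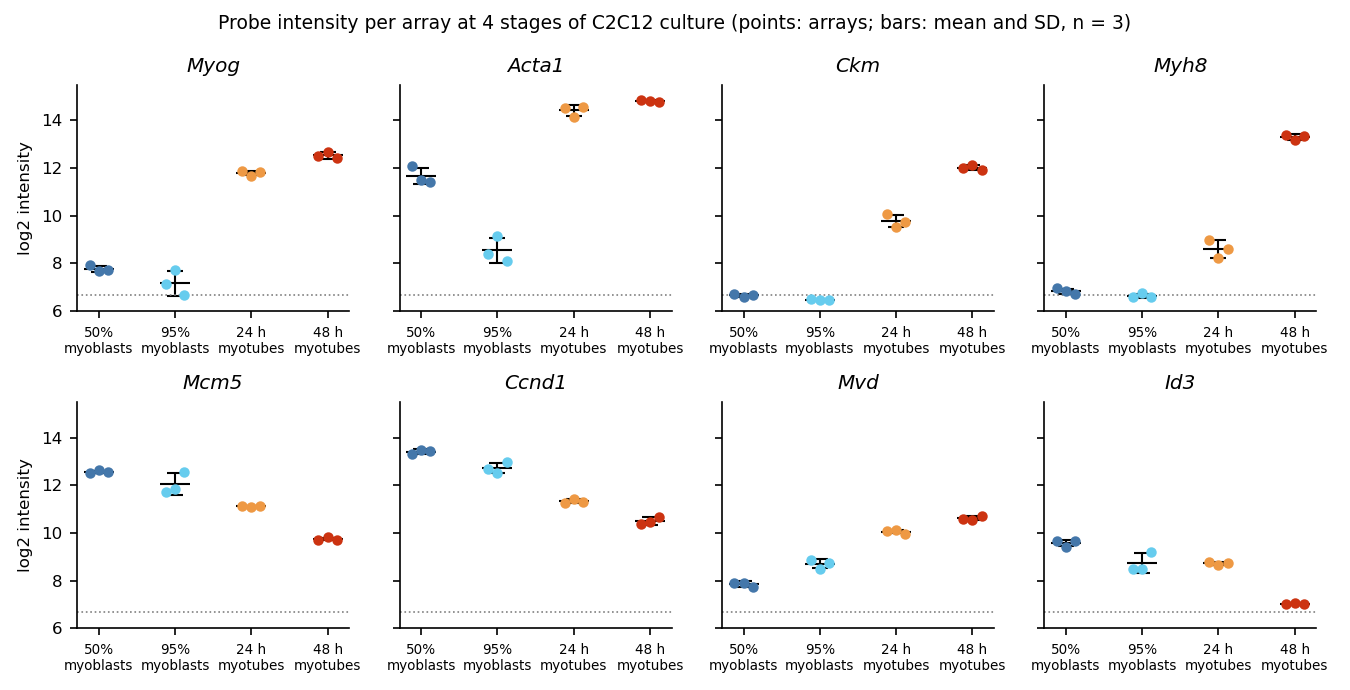
Log2 intensity of 8 genes at the 4 stages, with a point per array, bars for the mean and SD (n = 3), and a dotted line at the array median of 6.684. Myog, Acta1, Ckm and Myh8 are highest in 48 h myotubes, Mcm5, Ccnd1 and Id3 are highest at 50% confluence, and Mvd climbs through the 4 stages.

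Of 42 sarcomere genes 34 rose, 2 fell and 6 did not pass, with a median log2 change of 2.19 (adjusted p = 7.16e-26, or adjusted p = 0.0751 with an estimated correlation). Mylpf, Tnnc2 (6.49) and Actc1 (5.98) led the list, while Tpm1 (-0.34) and Tmod4 (-0.33, or -0.18 with the mean of its probes) fell. In the list of excitation-contraction coupling and calcium handling 16 of 21 genes rose and 0 fell, with a median of 1.55 (adjusted p = 3.11e-14, or adjusted p = 0.0540 with an estimated correlation). Examples were Atp2a1 (4.77), the calcium pump of fast muscle, Hrc (3.55) and Casq2 (3.12, from below the array median), which bind calcium in the sarcoplasmic reticulum. The costamere and dystrophin complex rose in 11 of 16 genes, with 5 not past and a median of 1.13 (adjusted p = 8.51e-10, or adjusted p = 0.0540 with an estimated correlation), led by Sgca (2.72) and Ank1 (2.56). Muscle energy metabolism rose in 12 of 19 genes and fell in 1, with a median of 0.73 (adjusted p = 6.67e-07, or adjusted p = 0.150 with an estimated correlation). Its members Mb (3.78), the oxygen-binding protein myoglobin, Cox6a2 (3.54, from below the array median) and Pgam2 (2.82) rose, and Pdk4 (-2.04), an inhibitor of pyruvate use, fell. Of 12 neuromuscular junction genes 9 rose and 3 did not pass (median 0.63, adjusted p = 1.09e-05, or adjusted p = 0.159 with an estimated correlation). Its acetylcholine receptor subunits Chrng and Chrnd rose by 3.91 and 1.34, and Chrng rose by 2.43 with the mean of its probes. Adjusted over the list alone, the junction list had 10 genes up and the other 4 lists had the counts given.

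Myogenic transcription factors rose in 6 of 9 genes, with 3 not past and a median of 0.30 (adjusted p = 9.92e-05, or adjusted p = 0.0948 with an estimated correlation). Myod1 rose by 0.60 (SE 0.07), Hes6 by 1.26 and Mef2c by 1.36 (SE 0.10), the last by 0.62 with the mean of its probes. The Myog change was 1.85 when only probes above the median on all 12 arrays were used, which selects another probe. Of 16 genes of cell cycle exit 8 rose, 1 fell and 7 did not pass (median 0.19, adjusted p = 0.000754, or adjusted p = 0.210 with an estimated correlation). The median of that list was 0.34 without array 1 of the 95% group. Cdkn1c (4.05) and Cdkn1a (1.71, SE 0.11), inhibitors of cyclin-dependent kinases, and Rb1 (1.55) rose, and Cdkn2d (-0.41) fell. DNA replication and G1/S fell in 32 of 40 genes and rose in 2 (median -0.63, adjusted p = 2.31e-09, or adjusted p = 0.281 with an estimated correlation), with Cdt1 (-1.03) and Fen1 (-0.93) down and E2f2 (1.33) up. Mitosis and G2/M fell in 29 of 35 genes and rose in 1 (median -0.56, adjusted p = 5.86e-12, or adjusted p = 0.159 with an estimated correlation), with Bub1b (-1.08), Aurka (-0.98) and Plk1 (-0.93) down. The 1 that rose, Kif23 (0.59), gave -0.17 with the mean of its probes and 0.33 without array 3 of the 95% group, and its adjusted p was 0.0561, 0.0686 and 0.0562 without arrays 1, 2 and 3 of the 24 h group. When adjusted over the list alone, 36 replication and 32 mitosis genes fell, and the other counts of this paragraph stayed as given.

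Cholesterol synthesis rose in 17 of 18 genes, with 1 not past and a median of 0.72 (adjusted p = 2.17e-12, or adjusted p = 0.0540 with an estimated correlation). Mvd, an enzyme of the mevalonate pathway, rose by 1.35 (SE 0.09), and Cyp51 and Msmo1 rose by 1.08 and 1.07. Fatty acid synthesis rose in 6 of 12 genes and fell in 0 (median 0.27, adjusted p = 0.00112, or adjusted p = 0.159 with an estimated correlation), with Scd1, a desaturase, up by 1.05. Of the insulin-like growth factor system 6 of 12 genes rose and 2 fell (median 0.20, adjusted p = 0.0328, or adjusted p = 0.285 with an estimated correlation), with Igf2 (4.49) and Igf2r (1.40) up and Irs2 (-0.27) down. Its median was 0.33 without array 2 and 0.09 without array 3 of the 95% group. Its adjusted p was 0.0522, 0.0563 and 0.0509 without arrays 1, 2 and 3 of the 50% group, and 0.0513 and 0.0505 without arrays 2 and 3 of the 48 h group. Imprinted genes rose in 4 of 10 with 6 not past (median 0.25, adjusted p = 0.0136, or adjusted p = 0.176 with an estimated correlation). Among them were Mest (2.95) and Dcn (4.05), the latter 2.08 with the mean of its probes. The imprinted median was 0.16 without array 3 of the 95% group. Of 12 Notch pathway genes 6 rose, 2 fell and 4 did not pass (median 0.44, adjusted p = 0.0149, or adjusted p = 0.0974 with an estimated correlation), with the targets Hey1 (1.98) and Heyl (1.92) and the ligand Dll1 (1.26) up. Numb (-0.28, or -0.12 with the mean of its probes) and Maml1 (-0.19, adjusted p = 0.0572 without array 1 of the 24 h group) fell. Of 33 genes of mitochondrial respiration 7 rose, 1 fell and 25 did not pass (median 0.08, adjusted p = 0.0250, or adjusted p = 0.176 with an estimated correlation), with Sdhb up by 0.30, or 0.19 with the mean of its probes. The whole mitochondrial list had an adjusted p of 0.0784 with the mean of probes, and 4 of its genes rose without array 1 or array 3 of the 24 h group. Adjusted over the list alone, 5 imprinted genes rose, 3 Notch genes fell, and 3 mitochondrial genes rose and 0 fell, while the other 3 lists kept their counts.

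The 7 largest falls included 3 proliferins, prolactin relatives of like sequence whose probes were not tested for shared signal: Prl2c3 (-2.59), Prl2c4 (-2.53) and Prl2c2 (-2.51). The other 4 were Hba-a1 (-2.10), an alpha-globin, Pdk4 (-2.04), the integrin Itgb7 (-1.89) and the ligand Wnt10a (-1.87). Id3, an inhibitor of basic helix-loop-helix factors, had a log2 change of -0.01 (adjusted p = 0.969). Without array 3 of the 95% group its change was 0.23 and passed the threshold. Filters on dim probes moved the medians of short lists: with no filter and with a level filter of 7.5, Notch gave 0.01 and 0.96, cell cycle exit 0.09 and 0.86, and the growth factor system 0.09 and 0.32. The myogenic factors gave 0.93 at 7.5, and without a filter energy metabolism gave 0.44 and imprinted genes 0.03, all past the threshold. In all, 4423 genes passed (1894 up, 2529 down), of which 364 changed at least 2-fold (280 up, 84 down). The groups did not overlap for 45.7% of genes, where chance gives 10%. Without array 3 of the 95% group 4703 genes passed, and 3983 genes were called in both fits, all 3983 in the same direction. Camera called 15 of 26 lists, and with an estimated correlation it called 0, with 21 by fry and 11 with an estimated correlation without array 3 of the 95% group. At an unadjusted p under 0.05, 5353 genes passed.

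**Figure D3:**
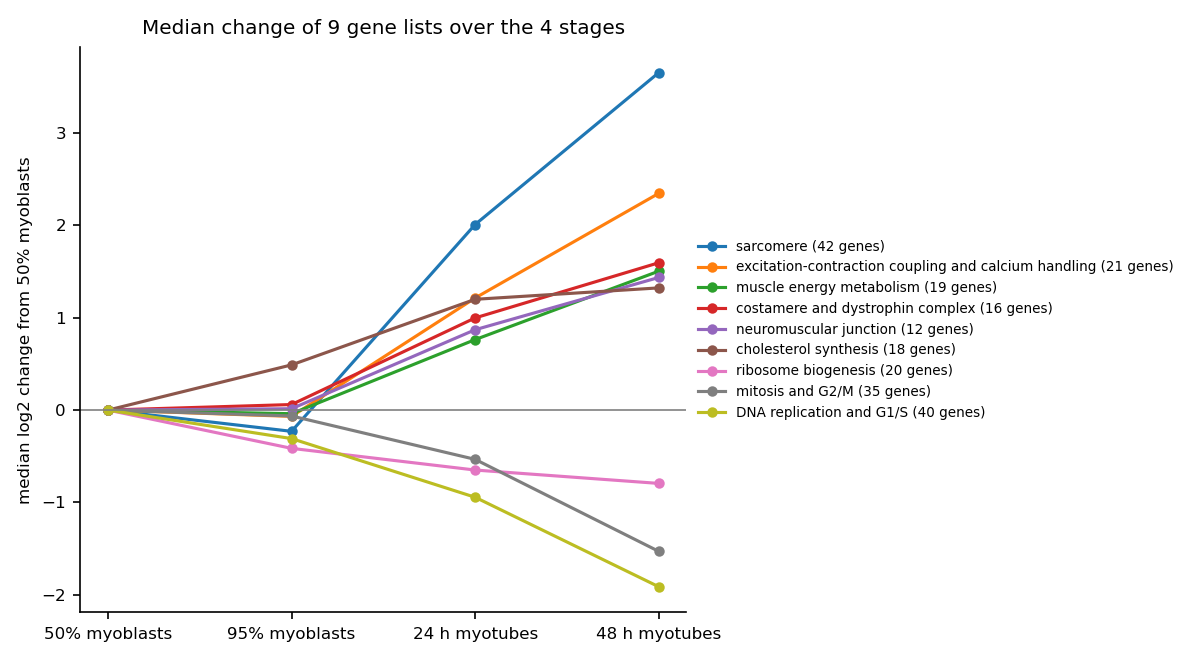
Median log2 change from 50% confluence of the measured members of 9 gene lists at the 4 stages, with a line per list. By 48 h the sarcomere list stands highest at 3.65 and DNA replication and G1/S lowest at -1.91.

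Myotubes at 48 h were compared with 50% confluent myoblasts to span the whole course. Myh8, the perinatal myosin heavy chain, rose from 6.83 ± 0.11 to 13.30 ± 0.11 (SD, n = 3), a log2 change of 6.46 (SE 0.15, adjusted p = 2.00e-11), and another probe gave 4.12. Ckm rose by 5.35 (SE 0.11, adjusted p = 1.25e-11) from below the array median, and Cdkn1c rose by 5.96 (62.2-fold). Fgf21, a secreted growth factor, rose 55.4-fold. Ccnd1 fell by 2.91 on the log2 scale (7.54-fold lower, adjusted p = 6.68e-10), and Id3 fell by 2.54 (5.83-fold lower, adjusted p = 4.06e-08). The proliferins Prl2c3, Prl2c4 and Prl2c2 were 83.5-fold, 76.5-fold and 70.9-fold lower.

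Of 42 sarcomere genes 41 rose and 1 fell, with a median of 3.65 (adjusted p = 5.68e-23, or adjusted p = 0.0752 with an estimated correlation). Actn2 (6.05, or 3.87 with the mean of its probes), Actc1 (6.01), Tnnc2 (5.81) and Tnni2 (5.77) rose, and Tpm1 (-1.49) fell. Acta1 rose by 3.16, from 11.66 ± 0.35 at 50% confluence. At 48 h Acta1 (14.82), Tnnc2 (15.04), Actc1 (14.49) and Tnni2 (14.41) lay near the highest value of the arrays, which can limit a rise. Excitation-contraction coupling rose in 18 of 21 genes and fell in 0 (median 2.35, adjusted p = 3.07e-11, or adjusted p = 0.0752 with an estimated correlation), with Atp2a1 (5.40), Hrc (5.05) and Casq2 (4.99) ahead. The costamere list rose in 14 of 16 genes, with 2 not past (median 1.60, adjusted p = 5.89e-08, or adjusted p = 0.0752 with an estimated correlation), led by Itgb1bp2 (3.95) and Ankrd2 (3.41). Energy metabolism rose in 16 of 19 genes and fell in 1 (median 1.5, adjusted p = 2.19e-09, or adjusted p = 0.0752 with an estimated correlation), with Cox6a2 (5.34), Pgam2 (5.08) and Mb (4.74) up and Pdk4 (-2.40) down. The neuromuscular junction rose in 10 of 12 genes, with 2 not past (median 1.44, adjusted p = 1.83e-05, or adjusted p = 0.143 with an estimated correlation), including Chrng (4.96) and Chrnd (2.23). Myogenic transcription factors rose in 8 of 9 genes, with 1 not past (median 0.74, adjusted p = 0.000127, or adjusted p = 0.0752 with an estimated correlation). Myog rose by 4.76 (27.1-fold), or 2.26 by another probe, Mef2c by 2.96, or 1.65 with the mean of its probes, and Myod1 by 0.74 (1.67-fold). When adjusted over the list alone, the counts of all 6 lists were as given.

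All 18 cholesterol synthesis genes rose (median 1.32, adjusted p = 3.12e-11, or adjusted p = 0.0752 with an estimated correlation), among them Mvd (2.78, 6.86-fold), Fdps (2.47) and Nsdhl (2.20). Fatty acid synthesis rose in 9 of 12 genes, with 3 not past (median 0.77, adjusted p = 0.000570, or adjusted p = 0.119 with an estimated correlation), including Scd1 (2.60) and Scd2 (2.34). Mitochondrial respiration rose in 22 of 33 genes and fell in 3, or in 5 without array 3 of the 95% group (median 0.30, adjusted p = 0.000754, or adjusted p = 0.0752 with an estimated correlation), with Ndufs3 (0.83) and Sdhc (0.62) up and Ndufa4 (-0.72) down. Of 16 genes of cell cycle exit 8 rose, 2 fell and 6 did not pass (median 0.20, adjusted p = 0.0139, or adjusted p = 0.367 with an estimated correlation). Cdkn1a (2.37, 5.17-fold) and Rb1 (2.16) rose, and Cdkn2d (-0.60) and Cdkn2c (-0.26) fell. The Notch pathway rose in 6 of 12 genes and fell in 1 (median 0.22, adjusted p = 0.0300, or adjusted p = 0.0987 with an estimated correlation), with Heyl (2.72, from below the array median), Hey1 (2.47) and Notch3 (2.11) up and Maml1 (-0.18, adjusted p = 0.0566 without array 3 of the 48 h group) down. Adjusted over the list alone, 4 mitochondrial and 2 Notch genes fell, with the other counts as given.

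DNA replication and G1/S fell in 37 of 40 genes and rose in 2 (median -1.91, adjusted p = 4.11e-15, or adjusted p = 0.172 with an estimated correlation), with Mcm5 (-2.81, 7.03-fold lower) and Tk1 (-2.80) down and E2f2 (2.52) and Cdk2 (0.37) up. Mitosis and G2/M fell in 34 of 35 genes (median -1.53, adjusted p = 5.47e-16, or adjusted p = 0.0987 with an estimated correlation), with Birc5 (-2.62), Mad2l1 (-2.33) and Plk1 (-2.30) down. The exception was Kif23, at 0.68, or -0.76 with the mean of its probes. Ribosome biogenesis fell in 16 of 20 genes, with 4 not past (median -0.79, adjusted p = 0.000754, or adjusted p = 0.460 with an estimated correlation), including Ncl (-1.36) and Nop56 (-1.25). Serum and growth factor response fell in 16 of 25 genes and rose in 5 (median -0.39, adjusted p = 0.0153, or adjusted p = 0.274 with an estimated correlation), with Dusp5 (-2.32) and Ier3 (-2.18) down and Klf4 (0.83) up. Of 9 reference genes often used for scaling 7 fell and 2 did not pass (median -0.55, adjusted p = 0.00137, or adjusted p = 0.0987 with an estimated correlation), such as Rpl13a (-0.71) and Hprt (-0.67). Centring the arrays on expressed probes left the reference median at -0.51 (adjusted p = 0.000970). The reference gene Actb had a change of -0.67, but 0.10 with the mean of its probes. When adjusted over the list alone, 6 serum response genes rose and 17 fell, with the other counts as given.

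Other large falls were in Csf1 (-3.39), a macrophage growth factor, the water channel Aqp5 (-3.29), smooth muscle Actg2 (-3.22) and Ccn2 (-3.21), connective tissue growth factor. With no filter on dim probes and with a level filter of 7.5, the Notch median was -0.02 and 1.51 and that of cell cycle exit 0.07 and 0.83. At 7.5 the myogenic factors gave 1.96 and energy metabolism 2.89, and without a filter fatty acid synthesis gave 0.50, all past the threshold. In all, 6710 genes passed (3153 up, 3557 down), of which 1328 changed at least 2-fold (666 up, 662 down). The groups did not overlap for 65.9% of genes, where chance gives 10%, and without array 3 of the 95% group 7269 genes passed. Camera called 16 lists, and with an estimated correlation it called 0, with 23 by fry and 5 with an estimated correlation without array 3 of the 95% group. At an unadjusted p under 0.05, 7121 genes passed.

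Myotubes at 48 h and at 24 h were compared for the second day of differentiation. Myh8 rose from 8.61 ± 0.37 to 13.30 ± 0.11 (SD, n = 3), a log2 change of 4.69 (SE 0.15, adjusted p = 1.33e-09). Actn2, which anchors actin at the Z-disc, rose by 3.82, Ryr1, the calcium release channel, by 3.19, and Tcap by 2.72. Ttn, the giant protein titin, rose by 3.75, or 1.26 with the mean of its 9 probes, of which 1 passed the other way. Ckm rose by 2.24 (SE 0.11, adjusted p = 2.44e-08). Acta1, at 14.41 and 14.82, lay near the highest value of the arrays, and its difference was 0.40 (adjusted p = 0.187, and 0.0439 with array weights or 0.00362 with the 6 arrays compared). Ccn2 fell by 2.80, and Id3 fell by 1.69 (SE 0.15, 3.22-fold lower). This comparison crosses the split of the arrays. Among called genes with 2 probes of a mean log2 level of at least 8, a second probe passed in the opposite direction in 58 of 919 (6.31%), against 7 of 807 (0.867%) for 24 h against 95%.

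Sarcomere genes rose in 37 of 42 and fell in 1, Tpm1 (-1.16), with a median of 1.34 (adjusted p = 2.10e-18, or adjusted p = 0.140 with an estimated correlation). Energy metabolism rose in 16 of 19 genes and fell in 0 (median 1.14, adjusted p = 4.59e-10, or adjusted p = 0.140 with an estimated correlation), with Mb (2.65), Cox6a2 (2.49) and Pgam2 (2.46). Excitation-contraction coupling rose in 17 of 21 genes and fell in 0 (median 1.02, adjusted p = 1.86e-09, or adjusted p = 0.140 with an estimated correlation), with Casq2 (2.42) and Hrc (1.81). The costamere list rose in 10 of 16 genes and fell in 0 (median 0.60, adjusted p = 0.000394, or adjusted p = 0.140 with an estimated correlation), with Itgb1bp2 (2.42) and Ankrd2 (2.29). The neuromuscular junction rose in 7 of 12 genes, with 5 not past (median 0.47, adjusted p = 0.00534, or adjusted p = 0.377 with an estimated correlation), including Ncam1 (1.58) and Chrnb1 (0.71), and in 4 genes without array 3 of the 24 h group or array 2 or 3 of the 48 h group. Myogenic transcription factors rose in 5 of 9 genes and fell in 1 (median 0.73, adjusted p = 0.0245, or adjusted p = 0.280 with an estimated correlation), with Mef2c (1.69, or 1.08 with the mean of its probes), Myod1 (0.85) and Myog (0.73, or 0.35 by another probe) up. The 1 that fell was Tcf12 (-0.24), which gave 0.23 with the mean of its probes and an adjusted p of 0.05004 without array 2 of the 24 h group and 0.0646 without array 1 of the 48 h group. Adjusted over the list alone, 38 sarcomere, 9 junction and 6 transcription factor genes rose, and the other 3 lists kept their counts.

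Mitosis and G2/M fell in 30 of 35 genes and rose in 0 (median -1.12, adjusted p = 5.75e-17, or adjusted p = 0.140 with an estimated correlation), with Birc5 (-1.81), Plk1 (-1.76) and Anln (-1.46). DNA replication and G1/S fell in 35 of 40 genes and rose in 2 (median -0.75, adjusted p = 1.60e-11, or adjusted p = 0.313 with an estimated correlation), with Gins2 (-1.72), Tk1 (-1.41) and Mcm5 (-1.37) down and E2f2 (0.67, or 0.44 with the mean of its probes) up. Progenitor genes and inhibitors of myogenesis fell in 9 of 15 and rose in 3 (median -0.37, adjusted p = 0.0380, or adjusted p = 0.140 with an estimated correlation). Id1 (-1.85) and Hes1 (-1.24), a repressor downstream of Notch, fell, and the receptors Notch1 (0.84) and Notch3 (0.81) rose. The progenitor list had an adjusted p of 0.0582 with the mean of probes and 0.125 with a level filter of 7.5. Reference genes fell in 6 of 9, with 3 not past (median -0.33, adjusted p = 0.00634, or adjusted p = 0.183 with an estimated correlation), such as Eef2 (-0.82), and centring on expressed probes left the median at -0.30. Ccnd1 changed by -0.83 and Cdkn1a by 0.43, or 0.71 with the mean of its probes. When adjusted over the list alone, 32 mitosis genes fell and the other counts stayed as given.

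Other large rises were in Erich5 (3.14) and Ccnt2 (2.88, or 0.86 with the mean of its probes). The largest falls were in the proliferins Prl2c3 (-4.37), Prl2c4 (-4.20) and Prl2c2 (-3.93), followed by Ccn2 and Islr (-2.12, or -1.18 with the mean of its probes), Nppb (-1.91) and Ccn1 (-1.91). Another probe of Ccn1 became the brightest when 1 array was left out, giving -1.09 without any single array of the 50% group or array 2 or 3 of the 95% group, -1.09 without array 2 of the 24 h group and -1.17 without array 3 of the 24 h group. Without a filter on dim probes the medians of the myogenic factors and the progenitor list were 0.45 and -0.13, and with the mean of probes those of the myogenic factors and excitation-contraction coupling were 0.40 and 0.68. Energy metabolism gave 0.72 with probes above the median on all 12 arrays. In all, 5328 genes passed (2706 up, 2622 down), of which 484 changed at least 2-fold (294 up, 190 down). The groups did not overlap for 62.0% of genes, where chance gives 10%. Camera called 10 lists, and with an estimated correlation it called 0, with 20 by fry and 1, mitosis, with an estimated correlation without array 3 of the 95% group. At an unadjusted p under 0.05, 6016 genes passed.

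Confluence was examined as 95% against 50% confluent myoblasts. Hba-a1 rose from 7.42 ± 0.06 to 10.40 ± 0.41 (SD, n = 3), a log2 change of 2.98 (SE 0.15, adjusted p = 3.29e-07). Acta1 fell by 3.11 (SE 0.23, 8.65-fold lower, adjusted p = 2.56e-06), from 11.66 ± 0.35 to 8.55 ± 0.52. Nsdhl, an enzyme of cholesterol synthesis, rose by 1.84, and Ccnd1, Myod1 and Id3 changed by -0.69, -0.71 and -0.85. This comparison crosses the split of the arrays too, and among called genes with 2 probes at that level a second probe passed in the opposite direction in 60 of 907 (6.62%), against 23 of 1221 (1.88%) for 48 h against 50%.

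Of 18 cholesterol synthesis genes 15 rose and 3 did not pass (median 0.49, adjusted p = 2.54e-09, or adjusted p = 0.303 with an estimated correlation), with Fdps (1.66, or 0.77 with the mean of its probes), Cyp51 (1.12) and Mvd (0.86) up. Sarcomere genes fell in 19 of 42, with 23 not past, or with 3 up without array 3 of the 95% group (median -0.23, adjusted p = 0.00140, or adjusted p = 0.848 with an estimated correlation). Examples were Mylpf (-2.93), Tnnc1 (-2.15) and Tnnc2 (-2.05). Myl1 had a change of -2.17 (adjusted p = 0.0208), with -1.16 for the mean of its probes and -1.14 without array 3 of the 95% group. Its adjusted p was 0.0695 without array 1 and 0.0507 without array 3 of the 50% group, and 0.104 with the 6 arrays compared. DNA replication and G1/S fell in 22 of 40 genes and rose in 2 (median -0.31, adjusted p = 0.000246, or adjusted p = 0.848 with an estimated correlation), with Pole (-1.05) and Chaf1a (-0.89) down and E2f2 (0.52) up. In that list 32 genes fell without array 3 of the 95% group, and 13 without array 1. YAP/TAZ-TEAD targets fell in 10 of 16 genes and rose in 2 (median -0.31, adjusted p = 0.00901, or adjusted p = 0.848 with an estimated correlation), with Ccn2 (-1.93) and Amotl2 (-1.15) down and Tgfb2 (0.58) up. Ribosome biogenesis fell in 10 of 20 genes, with 10 not past (median -0.41, adjusted p = 0.00883, or adjusted p = 0.877 with an estimated correlation), including Rrp12 (-1.18) and Polr1b (-0.96). Of its 20 genes 18 fell without array 3 of the 95% group (median -0.63), and without array 1 of that group 6 fell, with an adjusted p of 0.0666. The fits without array 3 of the 95% group passed 3 further lists: fatty acid synthesis, the interferon response and hypoxia and glycolysis then had medians of 0.19, 0.22 and 0.34, with adjusted p of 0.0305, 0.0147 and 0.0147, and with an estimated correlation as well adjusted p of 0.604, 0.604 and 0.364. By fry the adjusted p was 0.0505 for replication and 0.143 for ribosome biogenesis. Adjusted over the list alone, 16 cholesterol genes rose and 20 sarcomere, 25 replication and 11 YAP/TAZ genes fell, with the other counts as given.

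Other large rises were in Nrep (2.49), Islr (2.12, or 1.18 with the mean of its probes), Slc40a1 (2.11), which exports iron, Gsn (1.80, or 0.86 with the mean of its probes) and Idh1 (1.80). Erich5 (-2.37) and Myl4 (-2.02, or -1.01 with the mean of its probes) fell. Myog had a change of -0.59 (adjusted p = 0.0307), with -0.27 for the mean of its probes, 0.06 by another probe, and -0.34 (adjusted p = 0.0520) without array 3 of the 95% group. Without arrays 1, 2 and 3 of the 50% group its adjusted p was 0.101, 0.0544 and 0.0626, and without array 1 of the 95% group 0.0742. Ckm changed by -0.18 (adjusted p = 0.201, and 0.0459 with the 6 arrays compared), Mef2c by -0.09 (adjusted p = 0.523) and Cdkn1a by 0.23 (adjusted p = 0.131), with 0.39 (adjusted p = 1.32e-04) without array 3 of the 95% group and 0.34 (adjusted p = 0.00393) with array weights. The YAP/TAZ median was -0.14 without a filter, -0.16 with the mean of probes and -0.52 with a level filter of 7.5, where the sarcomere median was -0.35, and ribosome biogenesis gave -0.27 without a filter. In all, 4742 genes passed (2244 up, 2498 down), of which 224 changed at least 2-fold (91 up, 133 down). The groups did not overlap for 43.7% of genes, where chance gives 10%. Without array 3 of the 95% group 5853 genes passed, 358 of them at least 2-fold (176 up, 182 down), and 4533 genes were called in both fits, 4532 in the same direction. Camera called 5 lists (8 without array 2 or without array 3 of the 95% group, and 8 with array weights), and with an estimated correlation it called 0 (also 0 without array 3 of the 95% group), with 7 by fry. Of the 10 splits of these 6 arrays 9 gave at least 5 lists (highest other 9), so the splits do not set this count apart from chance. They cannot show that it is chance either, since each other split mixes the stages but keeps part of the difference between them. At an unadjusted p under 0.05, 5636 genes passed.

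The confluence step and the second day of differentiation share no array, and their calls were compared gene by gene. Of the genes called in both, 2192 moved in opposite directions, where independence gives 1064, and 606 moved the same way, where it gives 1062. Without array 3 of the 95% group 1271 moved the same way, and with array weights 1167. Those fits call other numbers of genes, so the 1062 does not apply to them, and their values under independence were not computed. The genes that fell and then rose numbered 1156 and included Erich5, Myl4, Flnc and Ttn, with 16 sarcomere genes and 7 genes of excitation-contraction coupling. Those that rose and then fell numbered 1036 and included Islr and Gsn, with 10 mitosis and 7 cholesterol synthesis genes. As a list, mitosis and G2/M did not pass by camera at confluence (adjusted p = 0.824). Of its 35 genes 10 rose and 6 fell there, but 8 rose and 14 fell without array 3 of the 95% group. Across genes, which are not independent replicates, the log2 changes correlated at r = -0.333 (rho = -0.311). Among the genes with 2 probes of a mean log2 level of at least 8, the second probe made the same turn, at any size, in 158 of 203 genes that fell and then rose and in 162 of 193 that rose and then fell. In all 1696 genes with 2 such probes, the change in the difference between the probes correlated at r = -0.751 (rho = -0.694) between the steps. Cavin1, chosen after its values were seen, had probes at -0.57 and 1.61 in the confluence step and 0.23 and -1.64 in the second day. For 24 h against 95% and 48 h against 50%, which also share no array and both set myotubes against myoblasts, the same correlation was 0.656.

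**Figure D4:**
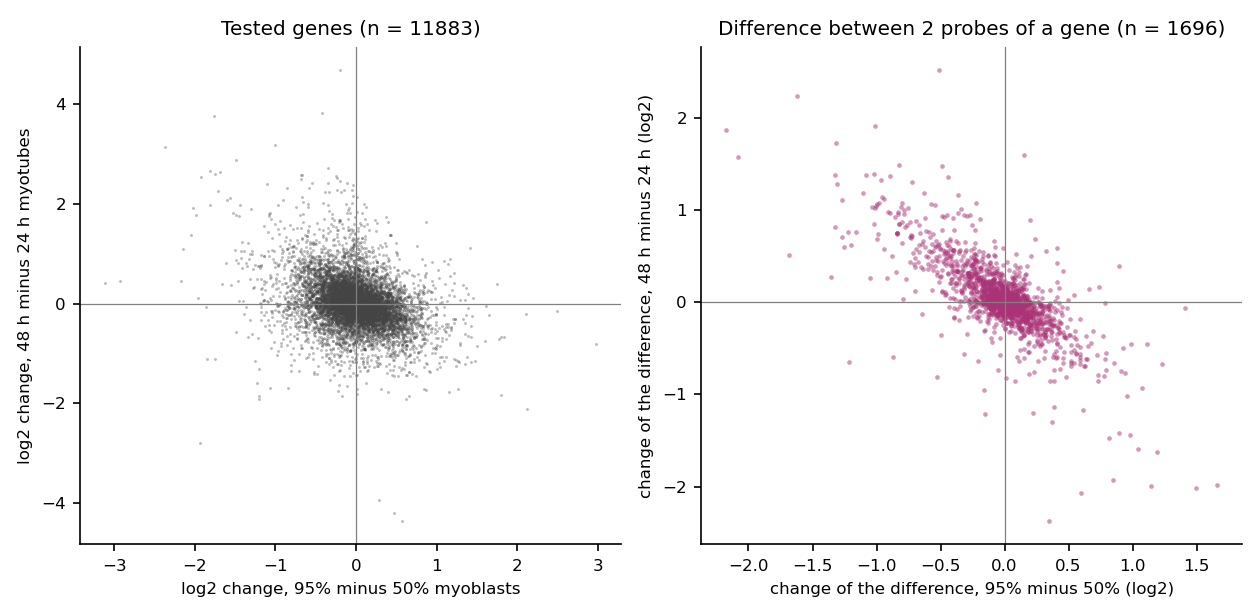
Log2 change from 24 h to 48 h of differentiation (vertical axis) against that from 50% to 95% confluence (horizontal axis), with a point per gene among 11883 genes on the left and, on the right, the change in the difference between 2 probes of a gene for 1696 genes. Points tilt downwards in both, weakly for genes (r of -0.333) and more closely for probe differences (r of -0.751).

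The confluence step and the first day of differentiation share the arrays of the 95% group, which pushes their differences apart. Of the genes called in both, 1176 moved the same way, where independence gives 889, and 1000 moved in opposite directions, where it gives 876. The log2 changes correlated at r = -0.0158 across genes (rho = 0.0906), with a covariance of -0.00245. In 100 simulations with no true change the shared arrays gave a covariance of -0.00381 on average. The simulated correlation of -0.500 follows from the shared arrays alone, so its distance from the observed r does not measure agreement between the steps.

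Endothelial markers rose in 3 of 6 genes and fell in 0 from 50% confluence to 48 h, with a median of 0.07 and an adjusted p of 0.223, or 3.27e-05 by fry. The 3 were Vwf (0.62), Cldn5 (0.38) and Tek (0.17), with highest group means of 7.15, 6.95 and 6.85. The endothelial medians were -0.00, 0.04 and 0.03 in the confluence step and the first and second day (adjusted p of 0.864, 0.635 and 0.256, and 3.17e-04 by fry on the second day, when 2 rose). Osteoblast markers (4 measured), adipocyte markers (4) and macrophage and leukocyte markers (2) had too few genes for a test, with medians from 50% to 48 h of -0.22, -0.04 and -0.51. Among them Bmp4 changed by -1.86, Pparg by -0.85 and Cd14 by -0.98, chosen after their values were seen. Extracellular matrix and fibroblast-type markers, a list whose genes myoblasts also express, rose in 8 of 29 and fell in 13 from 50% confluence to 48 h (median -0.17, adjusted p = 0.171). Their medians in the confluence step and the first and second day were -0.17, 0.22 and -0.10 (adjusted p of 0.155, 0.143 and 0.0588). By fry the adjusted p was 0.00182 over the whole course and 0.0152 in the second day. Without array 1 of the 95% group the adjusted p was 0.0367 in the confluence step and 0.0475 in the first day, or adjusted p of 0.901 and 0.477 with an estimated correlation. In the second day it was 0.0450 without array 3 of the 95% group, or adjusted p = 0.537 with an estimated correlation. Among them Dcn changed by 3.58 and Col1a1 by 1.14, and Lox by -2.07 and Timp1 by -1.81, again chosen after their values were seen.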

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

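Array weights, the other settings of eBayes, the filters, the fits to 6 arrays, the 2-fold requirement, fry and leaving out each array were planned, while centring on expressed probes, the level filter of 7.5 and the estimated correlation without array 3 of the 95% group, or without another array, were chosen after seeing the data. With each kept probe tested on its own, so with more tests, 8085 probes passed for 95% against 50%, 6743 for 24 h against 95%, 9144 for 48 h against 24 h, 10542 for 48 h against 50% and 14087 for any stage. The confluence step then shared 4197 opposite calls with the second day, and 1850 calls in the same and 1577 in the opposite direction with the first day. A 2-fold requirement left 224, 364, 484 and 1328 genes in the same order of the 4 comparisons. Array weights raised the calls shared by the confluence step and the second day to 1167 in the same direction, and the lists called at confluence to 8. Camera with an estimated correlation called 0, 0, 0 and 0 lists, with lowest adjusted p of 0.303, 0.0540, 0.140 and 0.0752, and without array 3 of the 95% group as well it called 0, 11, 1 and 5. Fry called 7, 21, 20 and 23. The cause of these differences was not tested.

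Leaving out each array in turn gave 3845 to 5853, 3577 to 4703, 4561 to 6270 and 6168 to 7269 genes in the 4 comparisons and 8154 to 8974 for any stage. Lists numbered 5 to 8, 14 to 17, 10 to 12 and 16 to 17, with 8 at confluence without array 2 or 3 of the 95% group. Lists also passed that did not pass with every array. In 48 h against 50% imprinted genes passed without any 1 of 9 arrays (median 0.54 and adjusted p 0.00453 without array 3 of the 95% group, or adjusted p = 0.0519 with an estimated correlation, and 0.167 to 0.295 without the other 8). Without that array the progenitor list passed in the first day (median 0.23, adjusted p = 0.0417, or adjusted p = 0.181 with an estimated correlation) and Notch in the second (adjusted p = 0.0398, or adjusted p = 0.105 with an estimated correlation). Without array 1 of the 95% group ribosome biogenesis passed in the first day (median -0.39, adjusted p = 0.00792, or adjusted p = 0.510 with an estimated correlation), but its median was -0.22 with every array and 0.07 without array 3 of the 95% group (adjusted p = 0.461). Calls shared in the same direction by the confluence step and the second day ranged from 445 to 1271, the latter without array 3 of the 95% group, and opposite calls from 1855 to 2649. With the first day, same calls ranged from 876 to 1507 and opposite calls from 809 to 1450.

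Directions reversed in a few values, and the cause was not tested except where another probe was used. Without a filter on dim probes the Notch median in 48 h against 50% was -0.023. With probes above the median on all 12 arrays the change of Myog at confluence was 0.0567, from another probe. With the mean of probes Kif23 changed by -0.17 (24 h against 95%) and -0.76 (48 h against 50%), Tcf12 by 0.23 (48 h against 24 h) and Actb by 0.10 (48 h against 50%). Id3 in 24 h against 95% ranged from -0.13 to 0.23 when 1 array was left out, and the 0.23, without array 3 of the 95% group, passed the threshold. Of the values of named genes under settings that keep every array, 2617 kept direction and side of the threshold, 33 fell short of it and 4 gained it. With 1 array left out, 3162 kept both, 64 fell short and 1 gained it, apart from the reversed value of Id3. For list medians 454 kept both and 51 fell short with every array, 546 and 6 with 1 array left out, and 17 and 29 with the estimated correlation without array 3 of the 95% group.

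The replicate block, which takes the replicate number of the labels as a block, gave 4781, 4452, 5388 and 6721 genes and 5, 16, 10 and 16 lists. Of 18 pairs of same-numbered arrays 5 had correlated deviations above 0.1 (range -0.09 to 0.33), so the numbers were not taken to pair the samples. The median was 0.0477 for same-numbered pairs and -0.0218 for other pairs. Pairs of replicate 1 and of replicate 3 were all positive, and those of replicate 2 all negative. A weak pairing by number is therefore not excluded. Background correction with other settings, median scaling and a chip block were not run, since the signal before normalization could not be tied to samples, all arrays have the same median and no chip is given. The deposited table, planned as an alternative source, was the source itself. Signal over background limits dim genes: filters left 19057 genes with no filter, 9628 with probes above the median on all 12 arrays and 7630 at a level of 7.5, and changes of genes near the median of 6.684 may be compressed.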

Other observations

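The tests of array 3 being nearer to the 50% stage and of its swap, and of a share of cells like the 24 h myotubes, were chosen after the result was seen, as were the genes named in this part, the count of second probes that turned and the extra condition on probes that move in opposite directions, with its size of 0.3 and level of 8. Myoblast fusion and adhesion did not pass by camera from 50% confluence to 48 h: 7 of 19 genes rose, 4 fell and 8 did not pass (7 and 4 adjusted over the list alone), with a median of 0.00 and an adjusted p of 0.321. Its medians in the confluence step, the first day and the second day were 0.03, -0.01 and 0.06, with adjusted p of 0.864, 0.187 and 0.652, and 0.04 in the first day without array 3 of the 95% group. By fry the list passed upwards over the whole course (adjusted p = 1.22e-05) and in the first and second day (adjusted p of 7.93e-04 and 0.00357), the first day against the sign of its median. Mymk, the fusion protein myomaker, changed by 3.97 in the first day and 4.94 over the whole course (adjusted p = 1.1e-10), Dysf, a membrane repair protein, by 2.91 and Cav3, a muscle caveolin, by 1.83. The integrin Itga3 changed by -2.24.

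The unfolded protein and amino acid stress response went both ways over the whole course, with 9 of 17 genes up, 6 down and 2 not past (median 0.41, adjusted p = 0.321, or 4.12e-06 by fry). Trib3 (2.34), Chac1 (1.62) and Ddit3 (1.33), genes of the amino acid stress branch, rose, and the chaperones Hsp90b1 (-0.60) and Calr (-0.41) fell. Its medians in the confluence step and the first and second day were 0.06, 0.06 and -0.07 (adjusted p of 0.244, 0.501 and 0.965, with 9.38e-04 and 0.00875 by fry in the first 2). Hypoxia and glycolysis had 8 of 19 genes up, 5 down and 6 not past (median 0.17, adjusted p = 0.381), with Aldoa (1.19) up and the glucose transporter Slc2a1 (-1.09) and Ldha (-0.68) down, and 11 up when adjusted over the list alone. Its step medians were 0.27, 0.03 and -0.30 (adjusted p of 0.0545, 0.560 and 0.227, with 0.0132 and 0.0184 by fry in the first and last). Without array 3 of the 95% group its confluence median was 0.34 (adjusted p = 0.0147, or adjusted p = 0.364 with an estimated correlation) and its first-day median -0.03, and without array 3 of the 50% group its adjusted p at confluence was 0.0378, or adjusted p = 0.948 with an estimated correlation. The interferon response rose in 5 of 15 genes and fell in 2 (median 0.13, adjusted p = 0.268), with step medians of 0.16, 0.03 and -0.21 (adjusted p of 0.155, 0.855 and 0.590). Without array 3 of the 95% group 8 of 16 interferon genes rose at confluence (median 0.22, adjusted p = 0.0147, or adjusted p = 0.604 with an estimated correlation), and the first-day median was -0.07. YAP/TAZ-TEAD targets fell in 11 of 16 genes and rose in 5 over the whole course (median -0.30, adjusted p = 0.107, or 8.05e-05 by fry). Among 3934 kept probes assigned to no gene, 1390, 848, 1634 and 1557 passed in the 95% against 50%, 24 h against 95%, 48 h against 24 h and 48 h against 50% comparisons.

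Genes moved 1 way from 50% to 95% confluence and back from 24 h to 48 h, and the correlation of the 2 changes was -0.265 without array 3 of the 95% group, which argues against that array as the whole cause. A hybridisation or scan batch shared by the 50% and 48 h arrays cannot be told apart from the stages: over probes below the median on all 12 arrays the correlation was -0.0838, between the bounds set for each outcome. A labelling or RNA processing batch cannot be told apart either: differences between 2 probes of a gene, at a level of 8 or more, correlated at -0.751, against -0.354 for the gene means, and met the bound set beforehand, but such a batch would coincide with the stages. Of 30 genes whose probes moved apart by at least 0.3 in opposite directions at confluence, 15 (50%) turned back in both probes, where chance gives 25% and the added condition asked for over 75%. In 0 of the 30 both probes kept their directions, where chance also gives 25%. In reverse 18 of 32 (56.3%) turned back in both probes and 1 kept both directions. The comparisons within the sides of the split had fewer such genes. For 24 h against 95%, set against 48 h against 50%, 0 of 4 turned back and 2 kept both directions. The reverse gave 0 of 15 turned back and 9 kept. Among genes that turned, the second probe made the same turn in 158 of 203 that fell first and 162 of 193 that rose first. A batch and a difference between the stages, the latter untested, therefore both stay open.

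Array 3 of the 95% group stood apart from arrays 1 and 2. Ribosome biogenesis was higher on it by a median of 0.77 and DNA replication by 0.46, and Tnnt1 (-2.74), Chrng (-2.68) and Ogn (-2.52) were lower. The residual SD of array 3 over dim probes was 1.03 times the mean of the other arrays. All arrays hold 1 set of values, which limits how far the spread of dim probes can differ between them. This ratio therefore cannot decide on noisier hybridisation. A swap is argued against by every array of the 50% group correlating better with its own group, by at least 0.0210. A culture nearer to the 50% stage cannot be told apart from other sources, since 37.9% of its squared deviation lay along the difference to that stage, between the bounds set for each outcome. No biological explanation was tested beyond the stage itself.

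Some muscle genes stood higher at 50% than at 95% confluence: 33 of 94 in 4 lists fell and 5 rose, and only the sarcomere list passed (adjusted p = 0.00140, or adjusted p = 0.848 with an estimated correlation), with 0.104 for excitation-contraction coupling, 0.996 for the junction and 0.864 for energy metabolism. Without array 3 of the 95% group 31 fell, which argues against that array as the cause, though 17 then rose, against 5 with it. A share of cells like the 24 h myotubes in the 50% cultures cannot be told apart from other sources: the share fitted to the fallen genes was 7.35%, and 47.8% of 23 abundant muscle genes lay below the level it predicts, with shares per gene from -9.52 to 19.5%. That share was the median over the 15 of these genes that had fallen. Genes that fell less thus lie below it partly by construction, so the 47.8% cannot decide. A labelling batch cannot be told apart either, since 70.9% of 55 other probes of the fallen genes were also lower at 95% (13 lower and 9 higher past the threshold), between the bounds set for each outcome. A difference in stage between the cultures stays open, untested.

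Other splits of the 6 arrays of each comparison, 10 with the real one, are too few for a share under 0.05. Each other split mixes the stages but keeps part of the difference between them, so its counts are not those of unchanged groups. In limma, 1 of the 10 splits, the real one, reached its count of genes in each comparison, with 4742, 4423, 5328 and 6710 genes against a highest other of 0. At an unadjusted p under 0.05 the highest others were 2693, 940, 216 and 257. For lists, 9 of the 10 splits reached the real count at confluence (5, highest other 9), 4 on the first day (15, highest other 17), 4 on the second day (10, highest other 12) and 1 over the whole course (16, highest other 14). Of 100 drawn splits of the 12 arrays into 4 groups, 1, the real one, reached 8578 genes for any stage, against a highest other of 5925. That share lies under 0.05 for arrays taken as independent. The labels do not say whether replicates were separate cultures, so chance differences between cultures cannot be excluded.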
